A study of Mus musculus with 2 samples.

How the data were processed

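The series holds 2 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from mouse splenic natural killer (NK) cells, 1 made with an in-house polyclonal antibody against Runx3 and 1 made with non-immune rabbit serum as control. Runx3 is a Runt-domain transcription factor expressed in NK cells and cytotoxic T cells. Per the labels' protocols, ICR mice received 2 injections of IL-15 bound to its receptor alpha chain, 2 days apart, and 40000000 NK cells were taken from the spleen by negative selection and a sort for NKp46, a receptor that marks NK cells. Chromatin was fixed in 1% formaldehyde and sheared to fragments of about 200 bp, and reads of 50 bp were aligned with ELAND. CASAVA 1.8.2 and the genome build mm9 are named in the submitters' processing notes; the protocol text writes the build as mmp9. The peak caller, its threshold and the way the control library entered the calling are not given in the sources used here.

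The authors deposited 1 list of Runx3 peaks, which has no header and gives a chromosome, a start and an end for each peak. The name it was deposited under contains the words "to small", which the sources used here do not explain, so it is open whether the list is the full set of called peaks or a reduced one. It holds no score, height, fold enrichment, p-value, strand or gene name. The starts count from 0, as in BED files, and are printed here counted from 1. With 1 library per antibody there is no replicate, and no values of the control library were used here, so no test between the Runx3 and the control library was made. The list holds no read counts, so the depth behind a peak is unknown and the recall of the calling cannot be stated.

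The gene table at hand is built on GRCm38, another build than mm9. Its coordinates were therefore not used, and no peak was assigned to a gene. The planned comparisons that need a genome or annotation of the peaks' build (location relative to genes, RUNX and other motifs, lists of NK cell genes and of markers of other spleen cells) or a score per peak were not analysed here. The items named are those fixed for this case before the data were examined: the 10 bins of 1 Mb with the most peaks, and the 5 widest peaks. The stretches of closely spaced peaks and the longest peak-free stretches were chosen after their values were seen.

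Widths, gaps and distances between the midpoints of neighbouring peaks were computed with Python 3.11.15 and numpy 2.4.6. Chromosome lengths of mm9 were not used, so the span of a chromosome was taken from the start of its first peak to the end of its last. Peaks per chromosome were compared with 1000 random draws in proportion to the spans, and spacing and bin counts with 1000 placements of the same peaks, with their widths and without overlap, at uniform positions on their own chromosome. Two-sided Monte Carlo p-values were taken from these draws, the smallest possible being 0.0020, and were adjusted by the Benjamini-Hochberg method over the 20 chromosomes. An adjusted p under 0.05 was called. Uniform draws treat peaks as independent, so the chromosome comparison was repeated with whole 1 Mb and 5 Mb bins permuted over the chromosomes, and spacing with placements that keep the number of peaks in each 1 Mb or 100 kb bin; both were added after the data were seen. Widths were compared between chromosomes with 100000 permutations of log2 width over the peaks. Intervals on counts are exact 95% Poisson intervals, which treat peaks as independent and cover counting error only. They leave out the clustering of peaks and the choice of the densest bins by their counts. Other alternatives were the peaks at or above the median width, joined peaks, other distances and shifted bins.

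The tests were tried on simulated lists of 19647 peaks. In 20 sets with no difference between chromosomes, 2 of 400 chromosome tests were called, and with 3 chromosomes at 1.25 times and 3 at 0.8 times the density all 60 of 60 were called each way. Peaks in these chromosome sets were drawn independently and not clustered, so the 2 of 400 calls give no false-call rate for clustered peaks. Spacing was called in 0 of 20 sets with uniform peaks and in 20 of 20 sets in which 500 peaks had been moved to 3 kb from another.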

Results

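Genome-wide occupancy of Runx3 was mapped by ChIP-seq in splenic NK cells that had been activated in the living mouse with IL-15, a cytokine that drives NK cell survival and proliferation. The data comprise 1 Runx3 library and 1 control library made with non-immune serum, each without a replicate, and the deposited result is a single list of Runx3 peaks in mm9 coordinates. Values below therefore describe this list, and whether it is the full or a reduced set of called peaks is not given in the sources used here. The RUNX motif was not sought in the peaks, so binding by Runx3 was not checked here. The error of a single value is a counting interval or the range of random placements, not a spread between animals, and the read depth behind the peaks is unknown.

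The list held 19647 Runx3 peaks on 19 autosomes and the X chromosome, and 0 on the Y chromosome. The peaks covered 13.3 Mb, which was 0.520% of the 2553 Mb spanned, at a mean of 7.69 peaks per Mb. The median width was 604 bp, with an interquartile range of 506 to 778 bp, and the central 90% lay between 397 and 1184 bp. The narrowest peak measured 177 bp, and 2050 peaks (10.4%) were wider than 1000 bp. No neighbouring peaks overlapped or touched, but 389 neighbouring pairs were separated by gaps of less than 100 bp, the smallest being 1 bp.

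**Figure D1:**
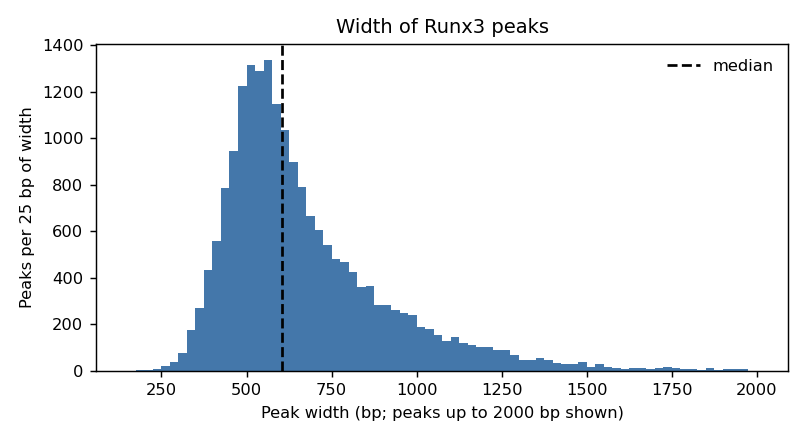
Histogram of peak width in bp (x axis, 25 bp steps, peaks up to 2000 bp) against the number of Runx3 peaks per step (y axis); the dashed line marks the median of 604 bp. The histogram is highest below the median and has a tail to wide peaks, of which 41 exceed 2000 bp and are not drawn.

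The 5 widest peaks measured 4.92 to 8.96 times the median width. The widest lay on chromosome 1 from 173487995 to 173493407 and measured 5413 bp. The next lay on chromosome 6 from 47596610 to 47601640 and measured 5031 bp. Peaks of 3622 bp on chromosome 2 (77781559 to 77785180), 3335 bp on chromosome 11 (74643701 to 74647035) and 2974 bp on chromosome 8 (48758589 to 48761562) followed. Each of the 5 had between 0 and 2 other peaks within 50 kb.

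The first comparison asked whether Runx3 peaks were spread evenly over the chromosomes. Chromosome 11 had the highest density, 14.0 peaks per Mb (1662 peaks), and chromosomes 19 and 17 followed with 11.9 and 11.0 per Mb. The X chromosome carried 312 peaks, 1.96 per Mb with a 95% counting interval of 1.74 to 2.18. Its density was 0.242 times that of the autosomes together, which held 8.08 peaks per Mb, and 0.359 times that of chromosome 3, the autosome with the lowest density at 5.44 per Mb. Chromosome 11 held 1.82 times the number of peaks that uniform placement gave, chromosome 19 held 1.55 times, chromosome 17 held 1.43 times, chromosome 7 held 1.24 times, and X held 0.254 times.

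Against uniform placement, 9 chromosomes held more peaks (2, 5, 7, 9, 10, 11, 15, 17 and 19) and 9 held fewer (1, 3, 6, 12, 13, 14, 16, 18 and X). Chromosomes 4 and 8 did not differ from it in this test (Benjamini-Hochberg adjusted Monte Carlo permutation p = 0.095 and 0.13). For chromosomes 11 and X the adjusted p was 0.0025, the smallest that 1000 draws gave after adjustment. Peaks were not independent of their neighbours, and when 1 Mb bins were permuted as units the adjusted p was under 0.05 for chromosomes 7, 11, 17 and 19, with more peaks, and for 3 and X, with fewer. Chromosome 1 lay below the central 95% of these permutations (1213 peaks against 1232 to 1765) but did not pass the adjustment (adjusted permutation p = 0.091). With 5 Mb bins, chromosome 11 (1662 peaks against a central 95% of 645 to 1275) and X (312 against 843 to 1627) were called, each with an adjusted permutation p of 0.020. The other chromosomes lay within the range that the clustering of peaks allowed. Neither the uniform draws nor the bin permutations took account of the genes and regulatory elements per Mb. The calls therefore do not show a preference of Runx3 for particular chromosomes.

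**Figure D2:**
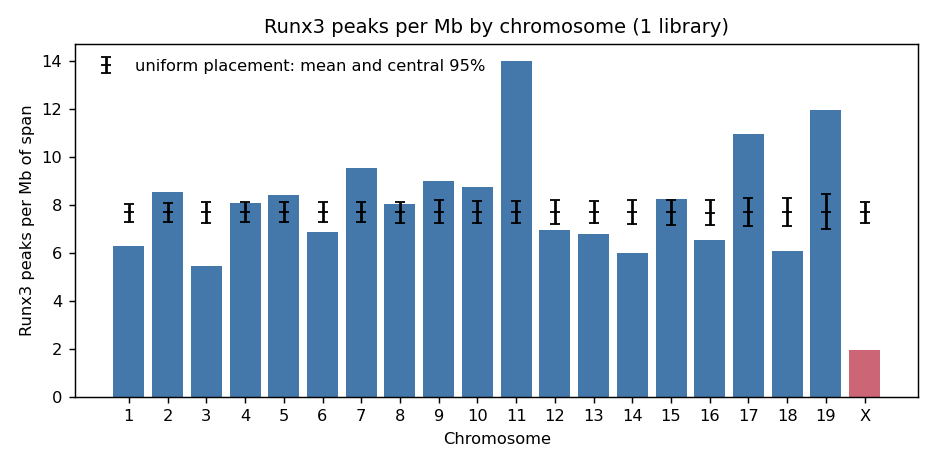
Runx3 peaks per Mb of span (y axis) for each chromosome (x axis); bars are the observed density in the 1 Runx3 library, X in red, and the black marks give the mean and central 95% of 1000 uniform placements. Chromosome 11 is highest at 14.0 peaks per Mb and X is lowest at 1.96.

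Peaks on the X chromosome were also narrower. Their median width was 566.5 bp, against medians between 577 bp (chromosome 18) and 618 bp (chromosome 8) on the autosomes. X was the 1 chromosome of 20 whose widths passed the test against the rest (difference in mean log2 width -0.12, adjusted permutation p = 0.00040). The permutation treated peaks as independent and was not repeated with whole bins permuted, so this p may be too small. The other 19 chromosomes did not pass this test; for chromosome 11 the difference was 0.02 (adjusted permutation p = 0.20), and for chromosome 12, the nearest to the threshold, it was -0.05 (adjusted p = 0.065).

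The second comparison asked whether Runx3 peaks lay in groups. The median distance between the midpoints of neighbouring peaks was 24.4 kb, whereas uniform placement on the same chromosomes gave 84.2 kb (central 95% of placements 83.0 to 85.5 kb). Of the 19627 neighbouring pairs, 6197 (31.6%) were at most 10 kb apart, which was 4.14 times the 7.62% of uniform placement (Monte Carlo permutation p = 0.0020, the smallest that 1000 placements can give). Within 5 kb the share was 21.1%, 5.85 times that of placement, and within 50 kb it was 66.8%, 1.97 times. The closer spacing held below the megabase scale: placements that kept the number of peaks in each 1 Mb bin gave 16.3% within 10 kb, and those that kept it in each 100 kb bin gave 24.4%, both lower than observed (permutation p = 0.0020 for each). The contrasts were smaller against these placements: the median distance was 42.2 kb with the 1 Mb counts kept and 27.7 kb with the 100 kb counts kept. The observed share within 50 kb was 1.21 and 1.01 times that placed. Single regions listed as several peaks could add close pairs. After joining gaps of up to 1000 bp, 24.1% of neighbours lay within 10 kb, against 14.3% with the 1 Mb counts kept. Joined peaks were not compared with placements that keep the 100 kb counts, so how much of that contrast remains is unknown.

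Over all pairs of peaks, not only neighbours, the excess over uniform placement was computed for midpoints 1 kb or more apart and was highest at the shortest of these distances. It was 8.14-fold for pairs 1 to 2 kb apart (1341 pairs), 4.45-fold at 5 to 10 kb, 2.88-fold at 50 to 100 kb and 1.67-fold at 500 to 1000 kb. Single regions listed as several peaks could add pairs at the shortest distances, and these values were not recomputed after joining close peaks. Relative to placements that kept the 1 Mb counts, the excess was 3.54-fold at 1 to 2 kb and 1.11-fold at 100 to 200 kb. The ratio was 0.98 at 200 to 500 kb and 0.93 at 500 to 1000 kb. Keeping the count in each bin fixes the number of pairs inside it, so an excess at short distances lowers the ratio at longer ones. These 2 ratios therefore do not show where the grouping ends. Against uniform placement, pairs 200 to 500 kb apart were still in excess, 2.02-fold.

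**Figure D3:**
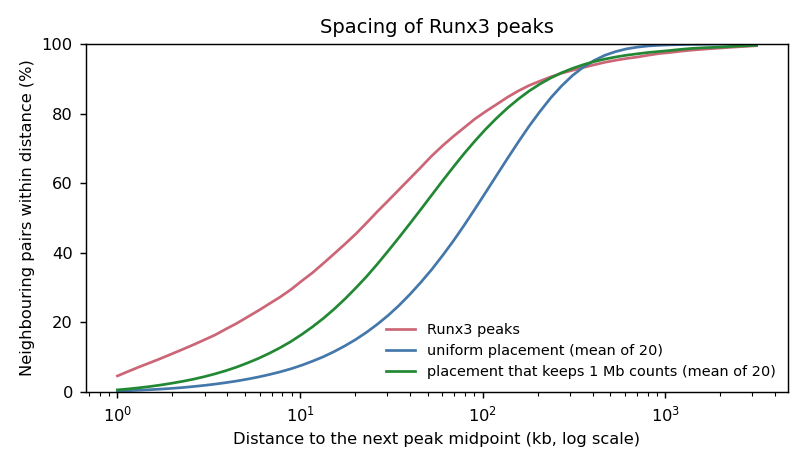
Percentage of neighbouring peak pairs (y axis) whose midpoints lie within a given distance in kb (x axis, log scale), for the Runx3 peaks (red) and for the mean of 20 placements made uniformly (blue) or with the number of peaks in each 1 Mb bin kept (green). At 10 kb the Runx3 peaks stand at 31.6%, the uniform placements at 7.62% and those that keep the 1 Mb counts at 16.3% (values from 1000 placements).

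When neighbours at most 10 kb apart were chained, 9750 peaks (49.6%) stood alone and the others formed 3700 stretches of 2 or more. Stretches of 5 or more peaks numbered 268, against a mean of 0.902 in uniform placements and 38.5 in placements that kept the 1 Mb counts (central 95% 28 to 51, permutation p = 0.0020). The largest stretch held 15 peaks in 47.3 kb on chromosome 11 (96964916 to 97012181). It was followed by 14 peaks in 51.8 kb on chromosome 15 (78393623 to 78445459), 13 peaks in 36.2 kb on chromosome 10 (79599816 to 79636047) and 13 peaks in 42.6 kb on chromosome 12 (106228877 to 106271480). Placements that kept the 1 Mb counts reached a stretch of 16 peaks at most and 8.76 on average, so the size of the largest stretch was less exceptional than the number of stretches (permutation p = 0.012). The stretches were not recomputed after joining close peaks, so single regions listed as several peaks could add to their number and size.

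The third comparison located the densest parts of the genome. In bins of 1 Mb, the median was 4 peaks, and the variance was 12.6 times the mean, against 1.79 times in uniform placements. The densest 10% of bins, 258 of 2572, held 40.1% of all peaks, against 19.4% in uniform placements, and 718 bins (27.9%) held no peak, against 28.7 bins (1.11%). Bins with 20 or more peaks numbered 287, against 11.4. The Monte Carlo permutation p was 0.0020 for each of these differences.

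The densest bin was on chromosome 10 from 80 to 81 Mb, with 80 peaks (95% counting interval 63.4 to 99.6), 10.4 times the genome mean; the fullest bin of a uniform placement held 24.5 peaks on average. Peaks covered 6.38% of this bin, and their median width of 667 bp lay above the genome median. The adjoining bin from 79 to 80 Mb was the third densest with 64 peaks (49.3 to 81.7). Chromosome 4 from 134 to 135 Mb ranked second with 69 peaks (53.7 to 87.3), on a chromosome whose overall density did not differ from uniform placement. Chromosome 19 from 5 to 6 Mb held 62 peaks, chromosome 7 held 58 from 52 to 53 Mb, and chromosome 11 held 55 from 115 to 116 Mb. Bins with 53 peaks lay on chromosome 7 from 31 to 32 Mb and from 134 to 135 Mb and on chromosome 11 from 120 to 121 Mb, and chromosome 15 held 52 peaks from 78 to 79 Mb. The order of these 10 bins was not tested. The stretch of 14 peaks on chromosome 15 and that of 13 on chromosome 10 fell within 2 of these bins.

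**Figure D4:**
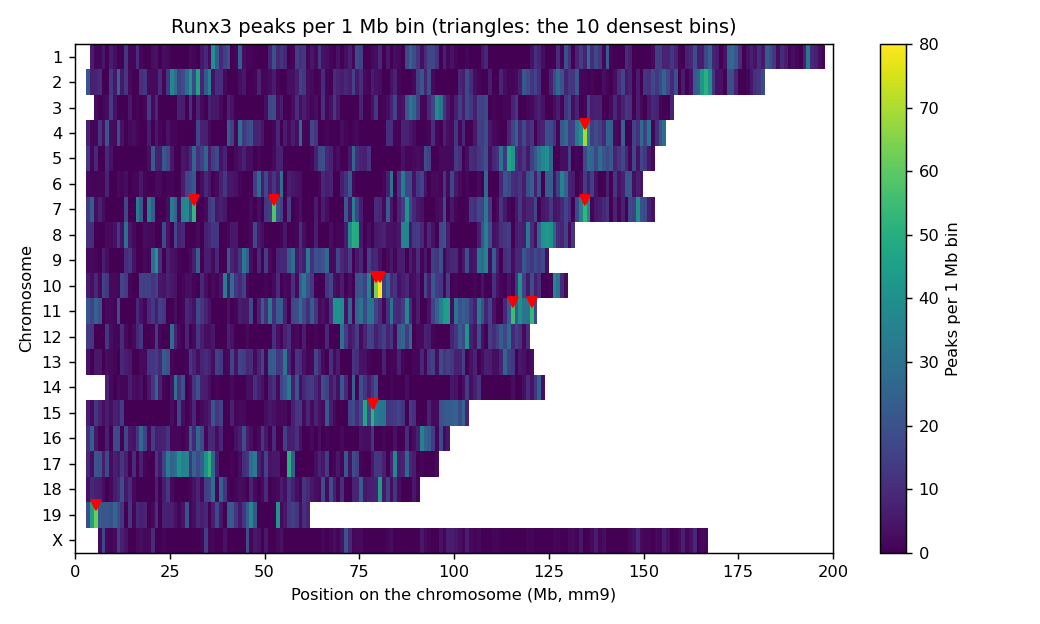
Map of Runx3 peaks per 1 Mb bin (colour, 0 to 80) along each chromosome (y axis) by position in Mb of mm9 (x axis), from the first to the last peak; red triangles mark the 10 densest bins. The 2 adjoining bins on chromosome 10 hold 64 and 80 peaks, and X stays dark over its length.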

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

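The joins across gaps of up to 100 and 1000 bp, the autosomes alone, the permuted bins, the placements that keep bin counts and the shifted bins were chosen after the data were seen; the other alternatives were fixed before. The density of X and the 2 measures of spacing were recomputed 19 times under settings that changed the peaks, the distance or the placement, and kept their direction and their call in 19 of 19. The bin permutations left the list unchanged, so the ratio for X stayed at 0.242 and only its call could change. Many settings share most of their peaks, so the 19 are not independent checks. Keeping the peaks at or above the median width left 9845 peaks by construction. The number of chromosomes called above and below expectation, 9 each under uniform placement, was 7 to 8 and 8 to 9 for the wider or joined peaks and the autosomes alone, and fell to 4 and 2 with 1 Mb bins permuted and to 1 and 1 with 5 Mb bins, because these permutations carry the clustering of peaks. The density of X relative to the autosomes was 0.190 among the wider peaks and 0.254 after joining gaps of up to 1000 bp. The ratio of neighbours within 10 kb ranged from 1.29 (100 kb counts kept) to 4.59 (wider peaks), each with permutation p = 0.0020. Of the 10 densest bins, 6 were among the densest 10 for the wider peaks, and 6 overlapped one when bins were shifted by 0.5 Mb; the cause was not tested. Joining book-ended peaks and leaving out Y changed nothing and so tested nothing. Uniform placement over whole chromosome lengths was not run. No paired analysis was possible because each antibody has 1 library. The list gives no read depth, so weak sites that were missed cannot be counted.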

Other observations

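The list also held long stretches without Runx3 peaks. There were 223 gaps of over 2 Mb between neighbouring peaks, 18 of them on X, and the longest measured 13.0 Mb on chromosome 15 (12754711 to 25772586), whereas the longest gap of a uniform placement averaged 3.21 Mb. Gaps of 11.6 Mb on chromosome 14 (87816431 to 99444505), 11.5 Mb on chromosome 1 (108693555 to 120207397) and 11.4 Mb on X (54580211 to 65931462) followed. Peaks were more frequent beyond the midpoint of the chromosomes' spans (at the higher position numbers) than before it, with 11441 peaks (58.2%) against 8206, and 14 of 20 chromosomes showed this direction (mean log2 ratio 0.42 ± 0.82 SD, n = 20, sign-flip permutation p = 0.035). Chromosomes 13, 14, 16, 17, 19 and X went the other way, down to a log2 ratio of -0.94 on chromosome 17. This comparison was not among those planned, and its p-value was not adjusted.

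Chromosomes with denser peaks also had higher median peak widths, by small amounts. The autosomal medians lay between 577 bp (chromosome 18) and 618 bp (chromosome 8), and no autosome passed the width test. The correlations below were not among the planned comparisons. Over the 20 chromosomes, density and median width correlated with Pearson's r = 0.77 (permutation p = 6e-05, adjusted 0.00036 over 6 correlations) and Spearman's rho = 0.76 (p = 0.00016, adjusted 0.00048). Without X and chromosome 11, the 2 farthest from the median density, r was 0.69 (adjusted permutation p = 0.0022), and over the 19 autosomes it was 0.66 (adjusted permutation p = 0.0027).

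The tests below were fixed before their results were seen, except that of peak width on X, which was chosen afterwards; the 95% intervals for X and for the crowding test were added after their values were seen. The design gives no second group of Runx3 libraries, so no biological explanation was tested for any of these patterns. The first pattern is the close spacing of peaks. Density that varies only at the 1 Mb scale is argued against, since neighbours within 10 kb were 1.94 times as frequent as in placements that keep the 1 Mb counts. Single regions listed as several peaks could add close pairs, and gaps were indeed most frequent at the shortest lengths, with 389 pairs per 100 bp below 100 bp and 123 per 100 bp at 500 to 1000 bp. After joining gaps of up to 1000 bp, which left 17786 peaks, the ratio was still 1.69, so splitting across such gaps does not account for the whole of this excess. Splitting across wider gaps was not tested, and joined peaks were not compared with placements that keep the 100 kb counts. Groups of genes and regulatory elements, or stretches that short reads cannot be placed in, remain open and were not tested.

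The second pattern is the low density of X. If only the narrowest peaks had been lost on X and the others kept their width, its median would lie above the autosomal median of 605 bp. Dropping the narrowest autosomal peaks to the same density would leave a median of 967 bp. The value on X was 566.5 bp (bootstrap 95% interval 553 to 586), which argues against such a loss as the whole cause. The condition written was stricter, a median below the lowest autosomal median of 577 bp, and the interval overlaps that value. It was chosen after the width on X was known. The test does not cover a loss that also narrowed the remaining peaks. An even loss of sites is not excluded. Of the 1 Mb bins on X, 48.4% held no peak (Wilson 95% interval 40.9 to 56.1), above the 36.2 to 46.9% of the 19 autosomes thinned to the density of X, which met the condition set beforehand against an even loss, but that condition had left out the counting error of X, and the interval overlaps the range. A lower number of X copies in male mice, lower signal from a silenced X copy in female mice, and repeats that short reads cannot be placed in stay open, since the list holds neither read counts nor the sex of the mice. Genes and regulatory elements per Mb were not compared between X and the autosomes, so their part stays open too.

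The third pattern is a weak relation of peak width to crowding. Across peaks, which are not independent, the correlation of width with the number of other peaks within 50 kb did not pass the test (Spearman's rho = -0.0023, permutation p = 0.74), and that with the number within 500 kb was weakly positive (rho = 0.056, p = 1e-05, the smallest that 100000 permutations can give; adjusted 1.5e-05 over 3 correlations). Adjacent sites joined into 1 listed peak might give this relation. Among the 9750 peaks with no other within 10 kb, rho was 0.053 (95% interval 0.033 to 0.072). That value lay above the bound of 0.05 set beforehand against joining, but by less than its own error. A peak with no other within 10 kb can itself hold joined sites, so the test cannot settle the question. Joining is neither excluded nor shown.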
